A study of Homo sapiens with 18 samples.

How the data were processed

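RNA was measured in 18 libraries labelled as primary human aortic endothelial cells, in 6 groups of 3 that were assigned from the sample labels. Per the labels' protocols, RNA was purified on columns and made into strand-marked libraries of polyadenylated RNA. The submitters' processing notes name bcl2fastq 2.19.1.403, STAR 2.7.9a, Partek, DESeq2 and the GRCh38 build, without their role or order. The annotation, the rule for counting reads, the use of strand and any filters are not given in the sources used here, so antisense genes and genes with near-identical copies are uncertain.

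The deposited table holds counts-per-million (CPM) values for 60528 features, to which the authors added 0.0001, per the name of the deposited table and its values. After 0.0001 was taken off, each library summed to the same total, as CPM do, and at least 99.94% of the low values were whole multiples of 1 read pair, within a tolerance of 0.1 of a step. This gave depths of 19018394 to 26195925 read pairs per library and a floor of 3 read pairs, or 0.115 to 0.158 CPM. The 4 features named by a bare number or an error mark, where the numbers may be gene symbols that a spreadsheet turned into dates, held 0.00061% to 0.0022% of a library and were left out. No scaling between libraries beyond the total is evident in the deposited CPM values.

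Genes at 1 CPM or more in at least 3 libraries were kept (14242), and log2(CPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 over all 18 libraries, with the preparation number as a block and an empirical Bayes prior with trend. Tests were two-sided, and genes with a Benjamini-Hochberg (BH) adjusted p under 0.05 were called changed. The series' design text states that the replicates are paired. In 45 of 45 pairs of same-numbered libraries, the deviations from the group means were correlated, at 0.571 to 0.944, and the highest correlation between different numbers was 0.187. Replicates have no order. With the block, p-values rest on how much the differences between groups varied over the 3 preparations, with 1 error pooled over all 6 groups.

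There were 35 gene lists, of interferon, immune, stress, metabolic, vascular and cell type marker genes, tested in each comparison with limma's camera at a preset correlation of 0.01 and with an estimated correlation, with BH adjustment over the 35 lists. Members were also adjusted over the list alone. List medians were computed again with members at 3 read pairs or fewer in every library of a group set to that floor. The genes named are the 6 largest changes in each direction (3 for ruxolitinib against untreated and FX1 against the other BCL6 compounds) among genes that passed, had a mean of at least 5 CPM and changed in 1 direction in 3 of 3 preparations, up to 4 members with the smallest adjusted p of each list described, and a fixed set of IFNγ pathway genes, of which 1 is not reported here. Genes outside that rule are said to have been chosen after their values were seen. Gene positions are from GENCODE v29 on GRCh38, matched by gene name.

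The groups, comparisons, test, block, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were pseudocounts of 0.1 and 1 CPM, no filter or a filter at 5 CPM, no block, a fit on only the groups compared, median-of-ratios scaling, other variance priors, and leaving out each preparation and each library in turn. Chosen after the data were seen were limma-voom on the recovered read pairs, subtraction of a fixed IFNγ library fraction from the ruxolitinib libraries, and reading the fit without preparation 2 as one without the preparation poor in endothelial transcripts. The residual response is the log2 difference from untreated cells after a compound divided by that with IFNγ alone, as a median over 337 genes raised by at least 1 log2 unit, in the fit over all preparations and in each preparation. Overlaps are given beside the number for independent lists and beside 50 simulations of unchanged groups against the shared libraries. Counts simulated for IFNγ against untreated cells (13959 genes, 200 changed) had 1 dispersion, 0.05. The fit recovered 51% of changes of 1 log2 unit and 100% of 2, with 2.6% false calls, and 0 calls in an unchanged comparison. In the data the spread varied, so these rates need not hold there. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.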

Results

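Gene expression was measured by mRNA sequencing in cells labelled as primary human aortic endothelial cells, the cells that line the inside of the aorta, grown to confluence in plates. The cells received interferon gamma (IFNγ), a cytokine made by T cells and natural killer cells that signals through the kinases JAK1 and JAK2, for 24 h. Before IFNγ, for 30 min, some cells were given 1 of 4 compounds, namely ruxolitinib, an inhibitor of JAK1 and JAK2, at 2 µM, or FX1, BI-3812 or BI-3802, which bind the transcriptional repressor BCL6, at 100 µM each. There were 6 groups of 3 libraries, 18 in all, which were untreated cells, IFNγ alone, and IFNγ after each of the 4 compounds. Each group held 1 library from each of 3 paired cell preparations, called preparations 1 to 3 below. Every compound was given with IFNγ, so effects of a compound on cells without IFNγ, or of its solvent, were not analysed here. Depth was 19018394 to 26195925 read pairs per library, with a median of 22112196, so 3 read pairs, the limit a count of 0 allows, corresponded to 0.115 to 0.158 counts-per-million (CPM). The 10 most abundant genes took 5.52% to 18.02% of a library. Levels are given as mean ± SD over the 3 preparations (n = 3), and log2 fold changes as estimate ± standard error from limma with preparation as a block. Adjusted p-values are from limma's two-sided test with Benjamini-Hochberg (BH) adjustment over 14242 genes. Floors cover counting error only. The p-values and the 95% intervals of fold changes rest on how much the differences between groups varied over these 3 preparations, pooled over all 6 groups.

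The preparations differed more than the treatments did. Preparation accounted for 52.3% of the variance of log2 values and treatment group for 34.8%, and the first principal component (41.3% of the variance) set preparation 2 apart from the others. In the 6 libraries of preparation 2, the level of VWF, the von Willebrand factor stored in endothelial cells, was 2.01 to 4.9 CPM, against 1326 to 4795 CPM in the other 12 libraries. CDH5, the cadherin of endothelial junctions, was at 1.54 to 15.3 CPM in preparation 2 and 585 to 1983 CPM in the others, and PECAM1, another junction protein, at 122 to 243 and 942 to 2578 CPM. The collagen gene COL1A1 was at 9844 to 41571 CPM in preparation 2, 248 to 721 CPM in preparation 1 and 9.78 to 15.8 CPM in preparation 3. The proteoglycan gene DCN was at 394 to 1057 CPM and the growth factor receptor gene PDGFRB at 366 to 911 CPM in preparation 2. Of 25 measured endothelial identity genes, 13 lay under 5% of the mean of the other preparations in preparation 2 in all 6 groups, while 11 lay over 10% of it in some group, and 6 of 9 measured fibroblast markers were at least 10 times higher there in all 6 groups. These genes were chosen after their values were seen. Because each preparation was present in every group, the additive part of this difference was taken up by the block, and some counts are also given without preparation 2.

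**Figure D1:**
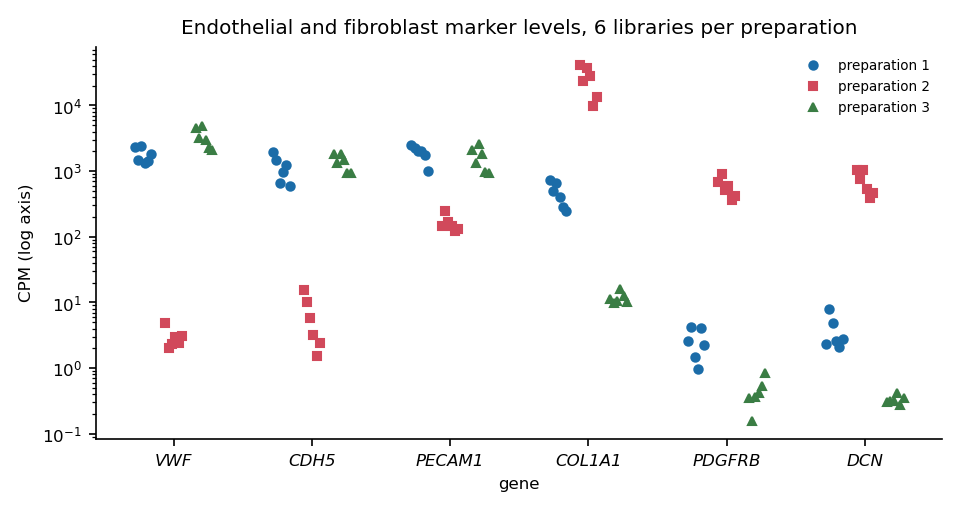
Levels (CPM, log axis) of the endothelial genes VWF, CDH5 and PECAM1 and of COL1A1, PDGFRB and DCN, 1 point per library and 6 libraries per preparation. The endothelial genes are lower and the other genes higher in every library of preparation 2, where VWF lies at 2.01 to 4.9 CPM.

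The comparison of IFNγ with untreated cells asked what the cytokine alone did. IFNγ turned on genes that were almost silent in untreated cells, with 341 genes higher and 21 lower among the 14242 tested. IDO1, the first enzyme of tryptophan breakdown, rose from 0.659 ± 0.306 to 1450 ± 207 CPM (log2 fold change 10.32 ± 0.31, adjusted p = 2.02e-12). The chemokines that bind CXCR3 rose as well, CXCL9 from 0.505 ± 0.23 to 1980 ± 1580 CPM (10.18 ± 0.71, adjusted p = 5.43e-08), CXCL10 from 0.504 ± 0.36 CPM to between 48.9 and 1170 CPM (8.54 ± 0.75, adjusted p = 7.13e-07) and CXCL11 to 1230 ± 1010 CPM (8.92 ± 0.77, adjusted p = 6.58e-07). CD74, the invariant chain of MHC class II, rose from 1.01 ± 0.391 to 974 ± 670 CPM (9.07 ± 0.37), and GBP5, an interferon-induced GTPase, to 826 ± 574 CPM (9.67 ± 0.81). The wide SDs come from levels that differed between preparations, and each of these genes was higher in 3 of 3 preparations. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of genes at low levels.

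Signalling and antigen presentation genes rose together. Of 18 measured STAT and IRF signalling genes, 15 rose and 0 fell (18 rose when adjusted over the list alone, camera adjusted p = 8.63e-65). Among them were IRF1, a transcription factor of the interferon response, which rose from 15.4 ± 5.54 to 888 ± 299 CPM (5.81 ± 0.29, adjusted p = 7.81e-10), BATF2 (6.61 ± 0.24), PARP14 (4.27 ± 0.21) and JAK2 (2.34 ± 0.26). CIITA, the master regulator of MHC class II genes, rose from 0.831 ± 0.491 to 307 ± 40.8 CPM (7.91 ± 0.49). Of 14 measured MHC class II genes, 12 rose and 0 fell (13 rose adjusted over the list alone, camera adjusted p = 6.21e-56), and the median log2 fold change was 5.6, or 5.91 with the 6 members that were at the counting floor in untreated cells set to that floor. HLA-DRA, an MHC class II chain, was at 0.082 ± 0.035 CPM in untreated cells, below the floor, and at 218 ± 177 CPM with IFNγ. All 18 measured MHC class I processing genes rose (18 adjusted over the list alone, camera adjusted p = 5.82e-77). Among them were TAP1, a subunit of the peptide transporter, at 4.99 ± 0.24, the immunoproteasome subunit PSMB9 at 5.89 ± 0.44 and HLA-B at 3.39 ± 0.31 on the log2 scale. HLA class I genes are close copies of each other, so how reads were divided among them is uncertain.

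Effector and antiviral genes followed the same direction. Of 17 measured guanylate binding proteins and other IFNγ effectors, 15 rose and 0 fell (16 rose adjusted over the list alone, camera adjusted p = 2.26e-77). GBP4 was at 7.87 ± 0.29, GBP1 at 6.31 ± 0.28 and GBP2 at 5.07 ± 0.24. The GBP genes are paralogs, and reads may have been split among them. Of 36 genes named for the type I interferon response, 34 rose and 0 fell (35 rose adjusted over the list alone, camera adjusted p = 2.5e-107). Examples were EPSTI1 (6.20 ± 0.33), IFITM1 (5.76 ± 0.42) and SAMD9L (4.0 ± 0.27). Of 13 measured interferon chemokines and cytokines, 10 rose and 0 fell (11 rose adjusted over the list alone, camera adjusted p = 5.58e-41). They included the membrane-bound chemokine CX3CL1 (6.76 ± 0.54). The list medians were 4.57, 4.29 and 4.28, and with members at the floor set to it the first and last became 5.08 and 4.91. Of 16 measured cell death genes linked to interferon, 10 rose and 0 fell (12 rose adjusted over the list alone, camera adjusted p = 4.54e-28). The number that rose was 6 without preparation 2 and 4 without the block. XAF1 was at 4.87 ± 0.36, CASP1 at 3.83 ± 0.33 and MLKL at 2.31 ± 0.22.

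Adhesion, checkpoint and complement genes changed in part. Of 15 measured adhesion and costimulation genes, 8 rose and 0 fell (9 rose adjusted over the list alone, camera adjusted p = 1.19e-10). The leukocyte adhesion receptor VCAM1 rose by 2.84 ± 0.59 (adjusted p = 0.00941) and CD274, which encodes the checkpoint ligand PD-L1, from 33.1 ± 33.2 to 208 ± 88.8 CPM (3.61 ± 0.81, adjusted p = 0.017). ICAM1 (2.52 ± 0.70, adjusted p = 0.0788) and SELE (-1.24 ± 0.80, adjusted p = 0.898, lower in 2 of 3 preparations) did not pass. Without preparation 2, VCAM1 had an adjusted p of 0.167. Of 14 measured complement genes, 8 rose and 0 fell (9 rose adjusted over the list alone, camera adjusted p = 2.85e-18). Among them were SERPING1 at 6.12 ± 0.49, C1R at 4.26 ± 0.56 and C1S at 4.94 ± 0.77, and C2 went from 0.0127 ± 0.022 CPM, below the floor, to 4.18 ± 3.34 CPM. Without preparation 2, 4 complement genes passed, and without the block 0 did, against 2 adhesion genes. All list results of IFNγ against untreated cells given so far also held with an estimated correlation between genes, with adjusted p-values of 0.0152 or less. BCL6 was at 78.2 ± 9.52 CPM with IFNγ and 37.2 ± 18 CPM without (1.16 ± 0.32, adjusted p = 0.0788), which did not pass, as SOCS3 did not (2.23 ± 0.61, adjusted p = 0.0716), whereas SOCS1, a feedback inhibitor of JAK kinases, rose by 4.36 ± 0.72 (adjusted p = 0.000964). JAK1 did not change detectably (0.05, adjusted p = 0.999).

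Fewer genes fell than rose with IFNγ in the fit over all groups. TNFRSF10D, a decoy receptor for the death ligand TRAIL, fell from 292 ± 164 to 39.4 ± 19.8 CPM (-2.85 ± 0.49, adjusted p = 0.0016). The cyclic GMP phosphodiesterase gene PDE5A (-1.84 ± 0.39), the noncoding RNAs AL590004.3 (-2.44 ± 0.38) and DANCR (-1.68 ± 0.35), MTURN (-1.63 ± 0.41) and ZNF704 (-1.59 ± 0.36) also fell, each in 3 of 3 preparations. Without preparation 2, TNFRSF10D (adjusted p = 0.0638), PDE5A (0.169), DANCR (0.148), MTURN (0.217) and ZNF704 (0.366) no longer passed, and MTURN did not under median-of-ratios scaling (0.07). Of 18 measured NF-κB inflammatory genes 1 passed (1 adjusted over the list alone, camera adjusted p = 0.0675), and 0 of 46 ribosomal protein, 0 of 25 extracellular matrix and 0 of 18 NRF2 oxidative stress genes did. As a set the ribosomal protein genes were lower (median -0.24, camera adjusted p = 9.07e-05, adjusted p = 0.714 with an estimated correlation). The count of changed genes was 362 with the block and 180 without it, 240 without preparation 1 and 238 without preparation 3, and limma-voom on the recovered read pairs gave 413. A fit on only the 2 groups gave 1549, with 784 higher and 765 lower.

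**Figure D2:**
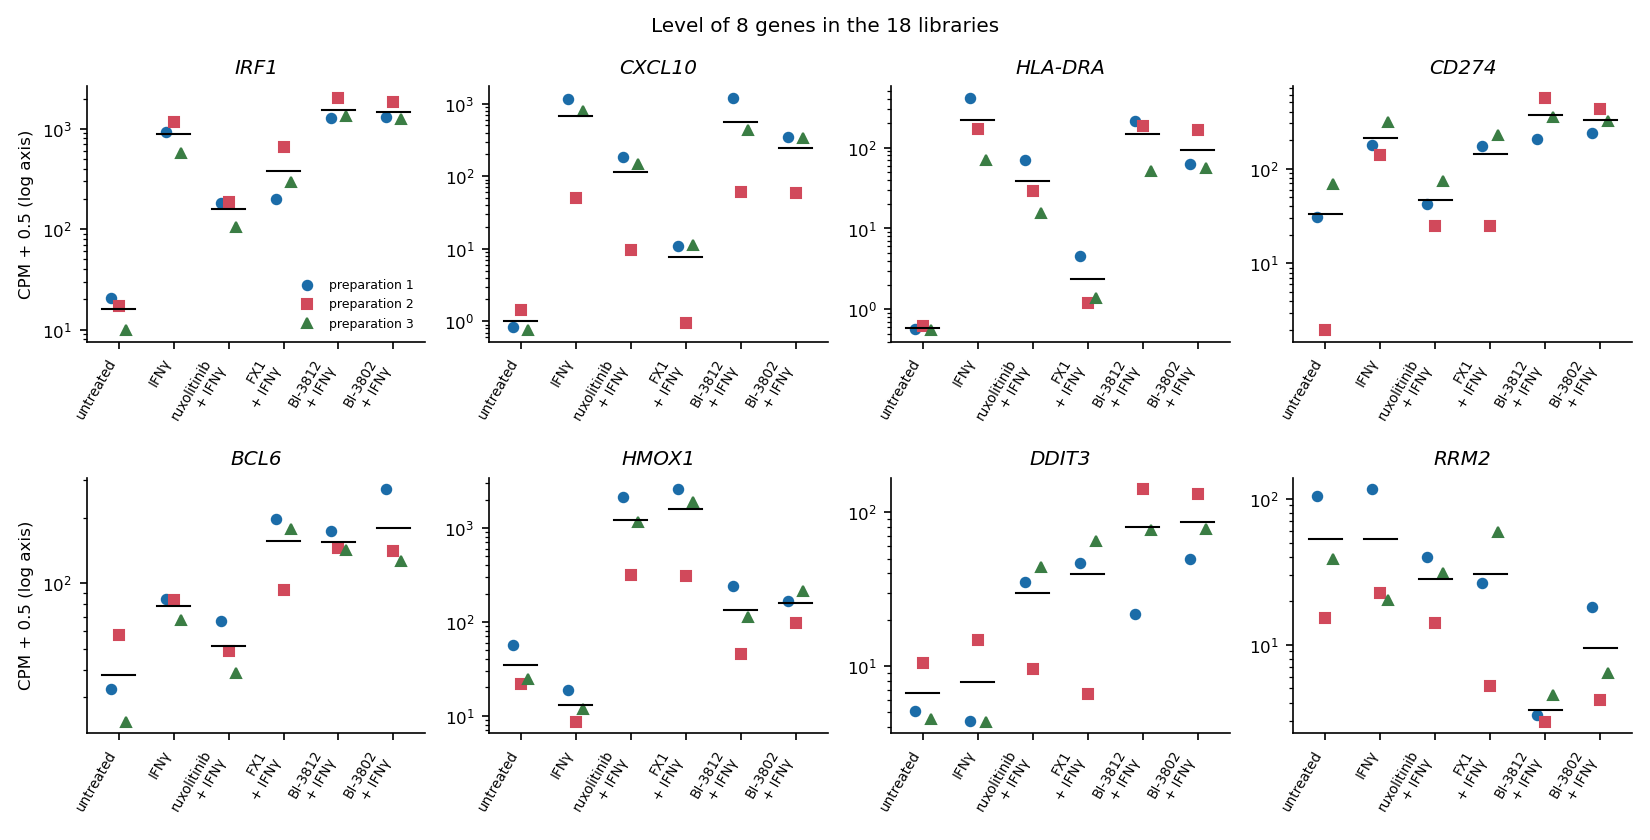
Levels (CPM + 0.5, log axis) of IRF1, CXCL10, HLA-DRA, CD274, BCL6, HMOX1, DDIT3 and RRM2 in the 6 groups, 1 point per library with a line at the mean of 3 preparations. HLA-DRA has a mean of 218 CPM with IFNγ, 37.8 CPM after ruxolitinib and 1.86 CPM after FX1.

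The key genes lie on the GRCh38 assembly (GENCODE v29 annotation) as follows. IRF1 is at chromosome 5, 132481609 to 132490798, and CIITA at chromosome 16, 10866222 to 10943021. HLA-DRA is at chromosome 6, 32439842 to 32445046, and CD74 at chromosome 5, 150401637 to 150412929. The genes CXCL9 (76001275 to 76007488), CXCL10 (76021117 to 76023497) and CXCL11 (76033682 to 76041415) are neighbours on chromosome 4. IDO1 is at chromosome 8, 39902275 to 39928444, CD274 at chromosome 9, 5450503 to 5470566, and BCL6 at chromosome 3, 187721377 to 187745727. HMOX1 is at chromosome 22, 35380361 to 35394214, DDIT3 at chromosome 12, 57516588 to 57521737, RRM2 at chromosome 2, 10120698 to 10131419, and SULT1B1 at chromosome 4, 69721162 to 69787961. Values are per whole gene, so exons and transcripts were not told apart.

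Ruxolitinib before IFNγ was compared with IFNγ alone to ask what JAK inhibition did to the response. Many IFNγ genes fell, and several of them, though not all, stayed above the untreated level. IRF1 fell from 888 ± 299 to 158 ± 46.4 CPM (-2.48 ± 0.29, adjusted p = 2.65e-05), CIITA from 307 ± 40.8 to 51.6 ± 10.2 CPM (-2.57 ± 0.49) and CD74 from 974 ± 670 to 161 ± 108 CPM (-2.56 ± 0.37). CXCL10 fell to 113 ± 91.8 CPM (-2.51 ± 0.75, adjusted p = 0.0146) and HLA-DRA from 218 ± 177 to 37.8 ± 28.3 CPM (-2.43 ± 0.51). JAK2 (-2.32 ± 0.26), SOCS1 (-2.47 ± 0.72), SOCS3 (-2.26 ± 0.61), CXCL9 (-2.54 ± 0.71) and CXCL11 (-2.76 ± 0.77) fell too. Large increases were seen in the nuclear receptor genes NR4A2, from 4.02 ± 6.05 to 271 ± 206 CPM (6.4 ± 0.57), and NR4A1 (5.59 ± 0.67). Heme oxygenase HMOX1 rose from 12.5 ± 5.15 to 1200 ± 913 CPM (6.21 ± 0.41, adjusted p = 2.48e-07) and the prostaglandin synthase PTGS2 from 25.7 ± 13.2 to 1170 ± 798 CPM (5.33 ± 0.33). FOSB (5.57 ± 1.12) and the neutrophil chemokine CXCL8 (5.05 ± 0.74) rose too.

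In 7 lists of interferon genes, members fell after ruxolitinib and none rose. In the STAT and IRF list 17 of 18 genes fell (17 adjusted over the list alone), with a median of -2.42 (camera adjusted p = 9.21e-09, held at adjusted p = 0.0097 with an estimated correlation). Its leading members were PARP9 (-2.44 ± 0.21), PARP14 (-2.47 ± 0.21), BATF2 (-2.53 ± 0.24) and DTX3L (-2.48 ± 0.24). In the MHC class II list 13 of 14 fell (13 adjusted over the list alone), with a median of -2.33 (camera adjusted p = 5.71e-05, adjusted p = 0.252 with an estimated correlation). They included CTSS (-2.42 ± 0.37) and HLA-DMA (-2.47 ± 0.43). All 18 MHC class I genes fell (18 adjusted over the list alone, 15 under median-of-ratios scaling), with a median of -1.60 (camera adjusted p = 2.34e-08, adjusted p = 0.175 with an estimated correlation). Examples were TAP1 (-2.35 ± 0.24) and NLRC5 (-2.41 ± 0.31). Of the 17 guanylate binding and effector genes 15 fell (16 adjusted over the list alone), with a median of -2.50 (camera adjusted p = 2.17e-08, adjusted p = 0.0998 with an estimated correlation). GBP4 went from 1780 ± 486 to 286 ± 85.7 CPM (-2.64 ± 0.29). Of the 36 type I interferon genes 31 fell (33 adjusted over the list alone, 25 without preparation 2, 16 without the block), with a median of -2.33 (camera adjusted p = 9.21e-09, adjusted p = 0.14 with an estimated correlation). They included SAMD9L (-2.64 ± 0.27) and DDX60 (-2.59 ± 0.31). Of the 13 chemokines 10 fell (10 adjusted over the list alone, 4 without the block; camera adjusted p = 0.00233, adjusted p = 0.0998 with an estimated correlation). Of the 16 cell death genes 13 fell (13 adjusted over the list alone, 6 without the block, camera adjusted p = 9.11e-05, adjusted p = 0.14 with an estimated correlation).

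Among genes that were nearly absent without IFNγ (at least 20 CPM with IFNγ and at most 2% of that in untreated cells), the ruxolitinib library held a nearly fixed percentage of the IFNγ library of the same preparation. The median was 16.6% in preparation 1 (48 genes), 16.2% in preparation 2 (47 genes) and 18.1% in preparation 3 (36 genes), and the SD of the log2 ratio across genes was 0.116, 0.097 and 0.21. The corresponding SD after FX1 was 1.602, 1.95 and 1.825, after BI-3812 it was 1.132, 1.157 and 1.337, and after BI-3802 it was 1.146, 1.108 and 1.306. Counting error alone gave 0.061, 0.073 and 0.073 in the ruxolitinib libraries.

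**Figure D3:**
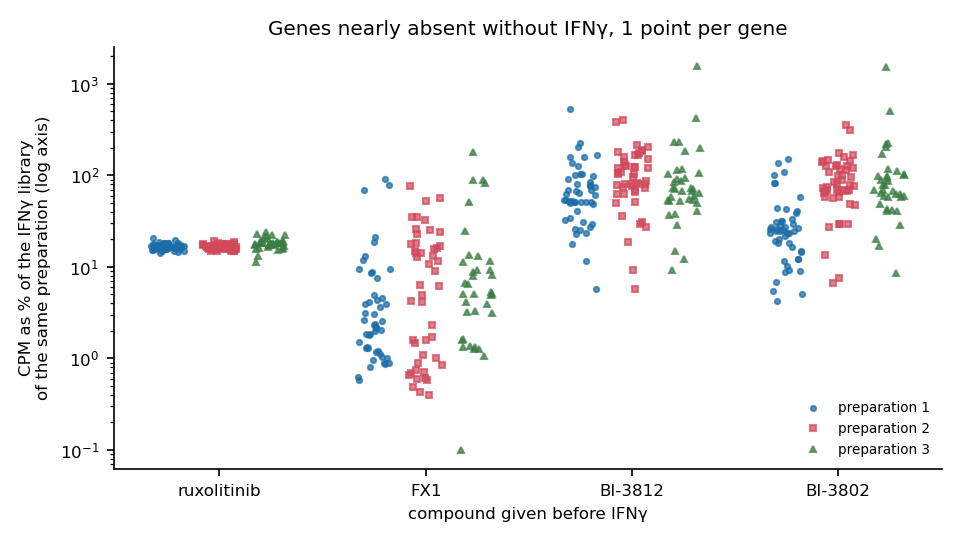
CPM after each compound as a percentage of the IFNγ library of the same preparation (log axis), 1 point per gene nearly absent without IFNγ, with values under 0.1% drawn at 0.1%. After ruxolitinib the points of preparations 1, 2 and 3 lie close to 16.6%, 16.2% and 18.1%, whereas after the other compounds they spread widely.

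Other groups of genes rose after ruxolitinib. All 46 measured ribosomal protein genes rose (46 adjusted over the list alone, median 1.27, camera adjusted p = 9.82e-36, adjusted p = 0.147 with an estimated correlation). Among them were RPS3A from 6.08 ± 0.782 to 44.2 ± 11.9 CPM (2.73 ± 0.30), RPS7 (2.22 ± 0.27) and RPL6 (1.69 ± 0.25). Ribosomal protein genes have many processed copies in the genome, so their absolute levels are uncertain. Of 20 p53 targets 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 2.98e-06, adjusted p = 0.14 with an estimated correlation). The cell cycle inhibitor CDKN1A went from 363 ± 145 to 3420 ± 1200 CPM (3.26 ± 0.38), and AEN (2.67 ± 0.34), GDF15 (4.38 ± 0.87) and ZMAT3 (2.04 ± 0.39) rose. Of 15 mitochondrially encoded transcripts 9 rose (10 adjusted over the list alone, 5 without preparation 2, 4 without the block, camera adjusted p = 1.4e-07, adjusted p = 0.175 with an estimated correlation). The largest rises were in the ribosomal RNAs MT-RNR1 (2.53 ± 0.28) and MT-RNR2 (1.51 ± 0.23). Of 18 NRF2 genes 5 rose and 0 fell (5 adjusted over the list alone, 3 without the block, camera adjusted p = 0.000196, adjusted p = 0.358 with an estimated correlation). They included the ferritin chains FTH1 (1.63 ± 0.27) and FTL (1.25 ± 0.28). Of 18 NF-κB genes 5 rose and 1, TNFAIP2 (-2.31 ± 0.32), fell (the same numbers adjusted over the list alone, 3 and 1 without preparation 2, 1 and 0 without the block, camera adjusted p = 0.00361, adjusted p = 0.335 with an estimated correlation). NFKBIA, an inhibitor of NF-κB, was among those that rose (1.64 ± 0.38). SELE, the endothelial selectin, rose from 2.12 ± 2.07 to 67 ± 94.6 CPM (2.92 ± 0.80, adjusted p = 0.0091), while ICAM1 (-0.86, adjusted p = 0.346), VCAM1 (-1.36, adjusted p = 0.0767) and BCL6 (-0.64 ± 0.32, adjusted p = 0.122) did not pass.

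In all, 1420 genes were higher and 4260 lower after ruxolitinib than with IFNγ alone. The median log2 fold change of all genes was -0.43, and with median-of-ratios scaling, which brought it to -0.10, 2292 were higher and 2103 lower. The calls of CD274 (-2.20 ± 0.81, adjusted p = 0.0398) and JAK1 (-0.69 ± 0.20, adjusted p = 0.0121) were lost under that scaling (adjusted p = 0.106 and 0.349), and 9 endothelial identity genes of 25 were lower without it but 1 with it (6 adjusted over the list alone; 3 without preparation 2, 0 without the block). The interferon lists kept their direction under both scalings and the ribosomal protein median became 1.68. The count of 5680 changed genes was 2520 without the block, 3494 without preparation 2, 2820 without preparation 3 and 3756 without the IFNγ library of preparation 1.

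Ruxolitinib with IFNγ was also set against untreated cells, to ask how far the cells stayed from the untreated state. IDO1 remained higher at 244 ± 47.3 against 0.659 ± 0.306 CPM (7.74 ± 0.31, adjusted p = 2.14e-10), as did CXCL9 (7.63 ± 0.71), GBP5 (7.11 ± 0.81), CD74 (6.52 ± 0.37), CXCL11 (6.17 ± 0.77), CXCL10 (6.04 ± 0.75), CIITA (5.33 ± 0.49) and IRF1 (3.33 ± 0.29). JAK2 (0.02 ± 0.26, adjusted p = 0.957) and SOCS3 (-0.03 ± 0.61, adjusted p = 0.973) did not pass, at 27.5 against 26.4 and 27.4 against 28.3 CPM. Of the lists, 11 of 14 MHC class II genes (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.14e-14) and 17 of 18 MHC class I genes (17 adjusted over the list alone, camera adjusted p = 3.48e-16) were higher than in untreated cells. So were 13 of 17 guanylate binding and effector genes (13 adjusted over the list alone, camera adjusted p = 7.64e-19) and 30 of 36 type I interferon genes (30 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.8e-22). Of 18 STAT and IRF genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone, 12 and 0 under median-of-ratios scaling, camera adjusted p = 2.1e-09), and of 13 chemokines 9 were higher (10 adjusted over the list alone, camera adjusted p = 1.58e-10). Of 16 cell death genes 5 were higher (5 adjusted over the list alone, 2 without preparation 2, 2 without the block, median 0, camera adjusted p = 0.011, adjusted p = 0.234 with an estimated correlation). The MHC class I call sat at adjusted p = 0.05 with an estimated correlation, and those of the MHC class II, effector, type I interferon, STAT and IRF, and chemokine lists held there. Without the block 6 STAT and IRF, 8 MHC class I and 17 type I interferon genes were higher. The ribosomal protein genes were again higher, 45 of 46 (46 adjusted over the list alone, 25 without the block, camera adjusted p = 8.67e-30, adjusted p = 0.135 with an estimated correlation). PDE5A (-2.70 ± 0.39), PNMA2 (-2.56 ± 0.50) and AL590004.3 (-2.84 ± 0.38) had the largest decreases among genes named by the fixed rule.

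The comparison gave 1304 genes higher and 4382 lower, or 2323 and 1763 under median-of-ratios scaling (all-gene median -0.48, then -0.08). The count of 5686 fell to 2501 without the block, 3484 without preparation 2, 2631 without preparation 3 and 3644 without the untreated library of preparation 1. Subtraction of the fixed IFNγ fraction from the ruxolitinib libraries was an alternative chosen after the data were seen. With it, IDO1 was at -1.18, IRF1 at -2.28 and CXCL10 at -0.10 against untreated cells, so their direction depended on it. The fraction was estimated from genes that IFNγ turned on, so these changes of direction follow largely from the construction.

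FX1 before IFNγ was compared with IFNγ alone to ask what this BCL6 compound did to the response. It lowered MHC class II and chemokine genes most. CD74 fell from 974 ± 670 to 8.93 ± 6.99 CPM (-6.64 ± 0.37, adjusted p = 4.28e-08), HLA-DRA from 218 ± 177 to 1.86 ± 1.87 CPM (-6.46 ± 0.51, adjusted p = 8.23e-07) and CXCL9 from 1980 ± 1580 to 20.9 ± 17.2 CPM (-6.57 ± 0.71). CXCL10 fell to 7.19 ± 5.85 CPM (-6.21 ± 0.75), and CX3CL1 (-6.20 ± 0.54) and CXCL11 (-6.12 ± 0.77) fell by as much. CIITA fell from 307 ± 40.8 to 16.4 ± 19.3 CPM (-4.83 ± 0.49), and the log2 fold change of VCAM1 was -4.92 ± 0.59 (adjusted p = 5.46e-05). IRF1 fell less, from 888 ± 299 to 383 ± 239 CPM (-1.33 ± 0.29, adjusted p = 0.00512). CD274 (-0.99 ± 0.81, adjusted p = 0.391), ICAM1 (-0.18 ± 0.70, adjusted p = 0.877) and SOCS3 (-0.93, adjusted p = 0.278) did not pass.

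The interferon lists fell unevenly with FX1. Of 14 MHC class II genes 13 fell (13 adjusted over the list alone, camera adjusted p = 5.32e-16), with a median of -4.69, or -4.79 with members at the floor set to it, and HLA-DMB (-4.75 ± 0.40) and CTSS (-4.30 ± 0.37) were among them. Of 13 chemokines 11 fell (12 adjusted over the list alone, camera adjusted p = 3.48e-09), with a median of -2.92, or -4.16 with the floor. Of 36 type I interferon genes 33 fell (33 adjusted over the list alone, camera adjusted p = 1.77e-20), with a median of -2.67. They included XAF1 (-5.02 ± 0.36), IFI44L (-5.23 ± 0.46) and EPSTI1 (-4.47 ± 0.33). Of 18 STAT and IRF genes 10 fell (13 adjusted over the list alone, camera adjusted p = 5.22e-06). BATF2 was at -3.05 ± 0.24, JAK2 at -2.41 ± 0.26 and STAT2 at -1.84 ± 0.26. These 4 lists held with an estimated correlation, at adjusted p-values of 0.0254 or less. Of 18 MHC class I genes 15 fell (17 adjusted over the list alone, camera adjusted p = 4.49e-10, adjusted p = 0.121 with an estimated correlation). Among them were HLA-F (-4.58 ± 0.32) and HLA-B (-2.23 ± 0.31). Of 17 guanylate binding and effector genes 10 fell (12 adjusted over the list alone, camera adjusted p = 1.79e-07, adjusted p = 0.0583 with an estimated correlation). Of 14 complement genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000377, adjusted p = 0.208 with an estimated correlation). Of 16 cell death genes 8 fell and 3 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.00637, adjusted p = 0.247 with an estimated correlation). Without the block the numbers that fell were 12 MHC class II, 6 chemokine, 20 type I interferon, 5 STAT and IRF, 9 MHC class I, 8 effector, 0 complement and 4 cell death genes.

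Other genes rose after FX1. HMOX1 rose from 12.5 ± 5.15 to 1600 ± 1170 CPM (6.54 ± 0.41, adjusted p = 1.11e-07), and OSGIN1 by 5.42 ± 0.42, CXCL8 by 5.23 ± 0.74, the matrix protease MMP10 by 5.0 ± 0.71 and FOSB by 4.74 ± 1.12. The antisense RNA LUCAT1 (chromosome 5, 91054834 to 91314547) rose from 0.176 ± 0.153 to 30 ± 11 CPM (5.45 ± 0.38), a value that is uncertain unless reads were counted by strand. Of 18 NRF2 genes 15 rose and 0 fell (18 adjusted over the list alone, 9 without preparation 2, 7 without the block), with a median of 2.14 (camera adjusted p = 2.53e-16, adjusted p = 0.0543 with an estimated correlation). They included SRXN1 (3.47 ± 0.44) and FTL (1.97 ± 0.28). Of 16 cytosolic heat shock genes 14 rose (15 adjusted over the list alone, 5 without the block, camera adjusted p = 3.08e-13, adjusted p = 0.0822 with an estimated correlation). The co-chaperone BAG3 was at 2.95 ± 0.48, FKBP4 at 2.17 ± 0.31 and the chaperone HSP90AA1 at 1.72 ± 0.24. Of 22 integrated stress response genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, 9 and 2 without preparation 2, 2 and 0 without the block, median 0.37, camera adjusted p = 0.0213, adjusted p = 0.589 with an estimated correlation). Of 18 hypoxia and glycolysis genes 13 rose (14 adjusted over the list alone, 6 without the block, camera adjusted p = 3.75e-13, held at adjusted p = 0.00165 with an estimated correlation). The growth factor VEGFA was at 2.66 ± 0.33, NDRG1 at 2.60 ± 0.42 and KDM3A at 2.28 ± 0.35. Of 21 lysosome and autophagy genes 9 rose and 1 fell (11 and 1 adjusted over the list alone, 11 and 0 under median-of-ratios scaling, 4 and 0 without the block, camera adjusted p = 3.14e-07, held at adjusted p = 0.0123 with an estimated correlation). The galactosidase GLA was at 2.82 ± 0.32 and the autophagy receptor SQSTM1 at 2.38 ± 0.37. Of 15 mitochondrially encoded transcripts 8 fell (11 adjusted over the list alone, 4 without the block, camera adjusted p = 0.000219, adjusted p = 0.344 with an estimated correlation). The largest falls were in MT-CO3 (-1.93 ± 0.26) and MT-CO1 (-1.55 ± 0.26).

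In all, 1122 genes were higher and 2171 lower after FX1, or 1479 and 1743 under median-of-ratios scaling (all-gene median -0.19, then -0.06). The count of 3293 was 572 without the block and 1122 in a fit on only the 2 groups. It was 341 without preparation 1, 1449 without preparation 3, 1145, 2159 and 2186 without the IFNγ libraries of preparations 1, 2 and 3, and 1187 without the FX1 library of preparation 1.

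BI-3812 before IFNγ was compared with IFNγ alone to ask the same of another BCL6 compound. CD74 differed by -0.10 (95% interval -0.88 to 0.69, adjusted p = 0.903) and HLA-DRA by -0.44 (-1.52 to 0.64, adjusted p = 0.64), and CIITA, CXCL10, CXCL11, CD274 and ICAM1 did not pass. CXCL9 fell from 1980 ± 1580 to 357 ± 394 CPM (-2.60 ± 0.71, adjusted p = 0.0396) and VCAM1 (-1.90 ± 0.59, adjusted p = 0.0646) did not pass. HMOX1 rose from 12.5 ± 5.15 to 134 ± 101 CPM (3.12 ± 0.41, adjusted p = 0.000572) and DDIT3, a transcription factor of the integrated stress response, from 7.31 ± 5.98 to 79.2 ± 59.8 CPM (3.24 ± 0.83, adjusted p = 0.0306). SULT1B1, a sulfotransferase, fell from 104 ± 45.4 to 4.33 ± 1.1 CPM (-4.34 ± 0.42, adjusted p = 0.000185), and RRM2, a subunit of ribonucleotide reductase, from 52.5 ± 54.6 to 3.06 ± 0.805 CPM (-3.42 ± 0.58, adjusted p = 0.00324).

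Other large increases with BI-3812 were in the histone gene H2BC4 (3.36 ± 0.42), which has near-identical copies, EGR1 (3.22 ± 0.85), ICAM4 (3.08 ± 0.76) and LUCAT1 (3.03 ± 0.38). Other large decreases were in the activin antagonist FST (-3.66 ± 0.70), FAM111B (-3.61 ± 0.52), KRT7 (-3.39 ± 0.51) and ZNF467 (-3.36 ± 0.39). Of 22 integrated stress response genes 9 rose and 0 fell (15 adjusted over the list alone, 4 without preparation 2, camera adjusted p = 9e-08, adjusted p = 0.253 with an estimated correlation). They included the amino acid transporter subunits SLC7A5 (1.94 ± 0.36) and SLC3A2 (1.78 ± 0.37). Of 18 NRF2 genes 8 rose (9 adjusted over the list alone, 3 without preparation 2, camera adjusted p = 1.11e-05, adjusted p = 0.331 with an estimated correlation). OSGIN1 was at 2.94 ± 0.42 and FTL at 1.73 ± 0.28. Of 30 proliferation genes 9 fell and 0 rose (15 adjusted over the list alone, 14 under median-of-ratios scaling, 1 without preparation 2, camera adjusted p = 7.2e-16, adjusted p = 0.253 with an estimated correlation). They included TYMS (-2.89 ± 0.60) and E2F1 (-2.07 ± 0.44). Of 25 endothelial identity genes 2, EMCN (-1.85 ± 0.40) and TEK (-1.78 ± 0.46), fell (6 adjusted over the list alone, 4 under median-of-ratios scaling, 1 without preparation 2, camera adjusted p = 1.4e-05, adjusted p = 0.253 with an estimated correlation). Of 25 extracellular matrix genes 5 fell and 2 rose (8 and 3 adjusted over the list alone, 5 and 1 under median-of-ratios scaling, 1 and 1 without preparation 2, camera adjusted p = 1.11e-05, adjusted p = 0.253 with an estimated correlation). The actin-binding protein TAGLN went from 912 ± 735 to 172 ± 149 CPM (-2.43 ± 0.31). Of 21 lysosome genes 6 rose (7 rose and 1 fell adjusted over the list alone, 3 rose under median-of-ratios scaling, 0 without preparation 2, camera adjusted p = 0.000153, adjusted p = 0.18 with an estimated correlation). Among them were SQSTM1 (2.18 ± 0.37) and NPC1 (1.98 ± 0.42).

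Few members of the interferon lists passed with BI-3812, although genes nearly absent without IFNγ spread widely, at 19.8% to 189.7% of the IFNγ level (5th to 95th percentile) in preparation 1. None of 14 MHC class II genes passed (0 adjusted over the list alone, median -0.32, camera adjusted p = 0.113), 3 of 18 MHC class I genes rose (0 under median-of-ratios scaling, without preparation 2 and without the block) with a median of 0.02 that became -0.15 under that scaling, and of 18 STAT and IRF genes 1 rose and 1 fell (0 and 1 under median-of-ratios scaling, 0 and 0 without preparation 2). Of 36 type I interferon genes 2, HERC5 (2.74 ± 0.52) and IFIT2 (2.11 ± 0.61, adjusted p = 0.0499), rose and 2, EPSTI1 (-1.22 ± 0.33) and IFITM2 (-1.20 ± 0.30), fell (2 and 2 adjusted over the list alone, 1 and 3 under median-of-ratios scaling, 0 and 0 without preparation 2, median -0.44, camera adjusted p = 0.00846, adjusted p = 0.577 with an estimated correlation). Of 13 chemokines 3 fell, CXCL9, IL32 (adjusted p = 0.00947) and TNFSF10 (-1.93 ± 0.54), and 0 rose (3 and 1 adjusted over the list alone, 1 and 0 without preparation 2, camera adjusted p = 0.0862). In all, 540 genes were higher and 374 lower, or 282 and 522 under median-of-ratios scaling (all-gene median 0.15, then -0.01). The count of 914 rested on the pairing and on single libraries, since it was 19 without the block, with 0 in each list given here for BI-3812. It was 310, 177 and 75 without preparations 1, 2 and 3, 200, 354 and 362 without their IFNγ libraries, and 229 and 233 without the BI-3812 libraries of preparations 2 and 3, 316 with no filter on low values, and 1540 in a fit on only the 2 groups. Of 39 named genes that passed, 17 did so without preparation 2 and 22 with no filter.

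BI-3802 before IFNγ was compared with IFNγ alone in the same way. HMOX1 rose from 12.5 ± 5.15 to 158 ± 57.2 CPM (3.61 ± 0.41, adjusted p = 0.000426) and DDIT3 from 7.31 ± 5.98 to 85.7 ± 41.9 CPM (3.61 ± 0.83, adjusted p = 0.0159). LUCAT1 (3.83 ± 0.38), MMP10 (3.76 ± 0.71), H2BC4 (3.67 ± 0.42) and EGR1 (3.63 ± 0.85) rose too. CXCL9 fell from 1980 ± 1580 to 155 ± 113 CPM (-3.42 ± 0.71, adjusted p = 0.011), as did VCAM1 (-2.61 ± 0.59, adjusted p = 0.0153) and SULT1B1 (-3.46 ± 0.42). FST (-3.45 ± 0.70), SHISA3 (-3.22 ± 0.65), PALMD (-3.12 ± 0.41) and UHRF1 (-3.07 ± 0.42), a regulator of DNA methylation, fell as well. CD74 (-0.82 ± 0.37, adjusted p = 0.172), HLA-DRA (-1.04 ± 0.51, adjusted p = 0.204), IRF1 (0.77 ± 0.29, adjusted p = 0.102) and CXCL10 (-0.92, adjusted p = 0.461) did not pass.

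Of 22 integrated stress response genes 13 rose and 0 fell with BI-3802 (17 adjusted over the list alone, 13 without preparation 2, camera adjusted p = 2.15e-09, adjusted p = 0.148 with an estimated correlation). They included asparagine synthetase ASNS (3.19 ± 0.53) and SLC7A5 (2.49 ± 0.36). Of 18 NRF2 genes 8 rose (11 adjusted over the list alone, 4 without preparation 2, camera adjusted p = 2.48e-07, adjusted p = 0.306 with an estimated correlation). OSGIN1 was at 3.43 ± 0.42 and SRXN1 at 3.06 ± 0.44. Of 30 proliferation genes 5 fell (11 adjusted over the list alone, 9 under median-of-ratios scaling, 0 without preparation 2, camera adjusted p = 8.24e-11, adjusted p = 0.338 with an estimated correlation). Among them were RRM2 (-2.27 ± 0.58), TYMS (-2.17 ± 0.60) and TPX2 (-1.76 ± 0.51). Of 25 endothelial identity genes 6 fell (10 adjusted over the list alone, 9 under median-of-ratios scaling, 5 without preparation 2, camera adjusted p = 1.85e-08, adjusted p = 0.137 with an estimated correlation). They included EMCN (-1.88 ± 0.40), the transcription factor SOX18 (-2.33 ± 0.50) and the nitric oxide synthase NOS3 (-1.56 ± 0.41). Of 25 extracellular matrix genes 5 fell and 3 rose (10 and 3 adjusted over the list alone, 3 and 2 without preparation 2, camera adjusted p = 1.42e-05, adjusted p = 0.148 with an estimated correlation). TAGLN was at -2.52 ± 0.31 and the collagenase MMP1 at 2.54 ± 0.48. Of 21 lysosome genes 6 rose (7 adjusted over the list alone, 3 under median-of-ratios scaling, 3 without preparation 2, camera adjusted p = 8.01e-05, adjusted p = 0.0803 with an estimated correlation). They included SQSTM1 (2.58 ± 0.37). Of 5 measured metallothioneins and their zinc transporter 3 rose (5 adjusted over the list alone, 2 without preparation 2, camera adjusted p = 0.00251, adjusted p = 0.148 with an estimated correlation). Among them were MT1X (1.95 ± 0.45) and MT1G, which went from 0.0301 ± 0.0269 CPM, below the floor, to 2.42 ± 2.06 CPM. These genes are close paralogs.

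As sets, the chemokines were lower with BI-3802 (median -0.87, camera adjusted p = 0.00109, adjusted p = 0.0803 with an estimated correlation), with 3 of 13 falling and 0 rising (4 and 1 adjusted over the list alone). Those 3 were CXCL9, TNFSF10 (-2.67 ± 0.54) and IL32 (-2.48 ± 0.44). The 36 type I interferon genes were lower as a set (median -0.70, camera adjusted p = 2.58e-05, adjusted p = 0.306 with an estimated correlation), with 3 falling, EPSTI1 (-1.41 ± 0.33), IFITM2 (-1.20 ± 0.30) and DHX58 (-1.0 ± 0.29), and 1, HERC5 (3.25 ± 0.52), rising (3 and 1 adjusted over the list alone, 5 and 1 under median-of-ratios scaling, 1 and 1 without preparation 2). The 14 MHC class II genes were lower as a set (median -0.95, camera adjusted p = 9.81e-05, adjusted p = 0.306 with an estimated correlation), with 1 falling (2 adjusted over the list alone, 2 under median-of-ratios scaling, 0 without preparation 2). The guanylate binding and effector list had a median of 0.12 but a mean of -0.38 and a lower camera direction (adjusted p = 0.0362, adjusted p = 0.415 with an estimated correlation), and its median became -0.10 under median-of-ratios scaling. In all, 862 genes were higher and 420 lower, or 427 and 685 under median-of-ratios scaling (all-gene median 0.16, then -0.03). The count of 1282 was 19 without the block, with 1 NRF2 gene and 0 in the other lists given here for BI-3802, and 524 with no filter on low values. It was 112, 512 and 35 without preparations 1, 2 and 3, 227, 557 and 520 without their IFNγ libraries and 274, 564 and 431 without their BI-3802 libraries, and 2444 in a fit on only the 2 groups. Of 45 named genes that passed, 36 did so without preparation 2 and 9 without preparation 3, and 30 with no filter.

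**Figure D4:**
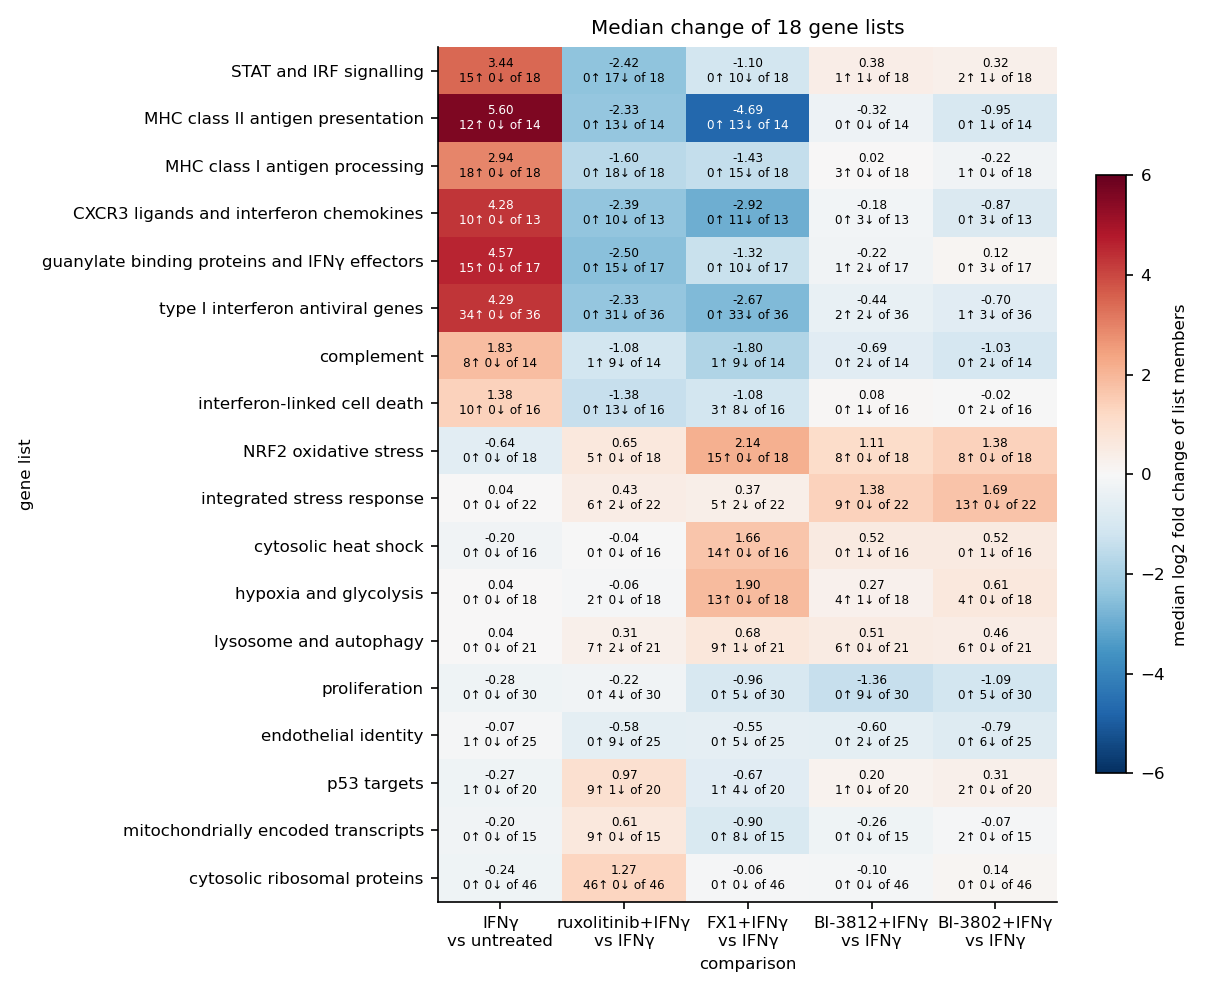
Median log2 fold change (colour) and number of members higher and lower (text) of 18 gene lists in 5 comparisons. MHC class II has a median of 5.6 with IFNγ, -2.33 after ruxolitinib and -4.69 after FX1, and ribosomal proteins have a median of 1.27 after ruxolitinib; the MHC class I median of 0.02 after BI-3812 becomes -0.15 and the effector median of 0.12 after BI-3802 becomes -0.10 under median-of-ratios scaling.

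BI-3802 and BI-3812 were given at the same dose and time, and their libraries were compared directly to ask whether these related BCL6 compounds differed. No gene passed in limma (0 of 14242), 25 genes had an unadjusted p under 0.05, and limma-voom called 0. Those 25 are far fewer than the share of 0.05 that a well-calibrated test gives without any difference. The error was pooled over all 6 groups, whereas this pair had SDs of the log2 ratio of 0.23 and 0.12 in preparations 2 and 3. The other 42 pairs of libraries of 1 preparation had at least 0.416. The 0 calls therefore do not show that the compounds act alike, and the intervals below rest on the same error. For 10722 genes (75.3%) the 95% interval of the difference lay within 1 log2 unit of 0, and the median interval reached 0.67 to either side, so for the remaining genes a larger difference was not excluded. The interval was -0.54 to 0.82 for BCL6 (0.14), -0.67 to 0.56 for IRF1 (-0.06), -1.50 to 0.06 for CD74 (-0.72), -1.68 to 0.48 for HLA-DRA (-0.60), -2.32 to 0.69 for CXCL9 (-0.82) and -2.31 to 0.84 for CXCL10 (-0.73), with BI-3802 minus BI-3812 as the direction. Of the 337 genes that IFNγ induced, 279 had a lower estimate with BI-3802 (median -0.20), and 175 had intervals within 1 log2 unit. As sets, chemokines (median -0.48, camera adjusted p = 2.24e-06, held at adjusted p = 0.0118 with an estimated correlation) and MHC class II genes (median -0.58, camera adjusted p = 2.3e-11, adjusted p = 0.132 with an estimated correlation) were lower with BI-3802, although no member of any list passed, over all genes or adjusted over the list alone. This difference lay mainly in preparation 1, as values chosen after they were seen show. The median differences in preparations 1, 2 and 3 were -1.73, -0.13 and -0.10 for the chemokines and -1.74, -0.21 and 0.11 for MHC class II. CD74 went from 1670 CPM with BI-3812 to 434 CPM with BI-3802 in preparation 1, 810 to 697 CPM in preparation 2 and 305 to 304 CPM in preparation 3.

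FX1 was compared with BI-3812 and with BI-3802 at the same dose and time, for the same purpose. MHC class II genes were lower with FX1 than with either, 14 of 14 against BI-3812 (median -4.17, or -4.58 with the floor, camera adjusted p = 1.24e-13, adjusted p = 0.05 with an estimated correlation) and 14 of 14 against BI-3802 (median -3.60, or -4.01 with the floor, camera adjusted p = 1.67e-12, adjusted p = 0.0657 with an estimated correlation). CD74 differed by -6.55 ± 0.37 (adjusted p = 5.38e-08) and -5.83 ± 0.37 (adjusted p = 3.33e-07), HLA-DRA by -6.02 ± 0.51 and -5.41 ± 0.51, CXCL10 by -6.02 ± 0.75 and -5.29 ± 0.75, and IRF1 by -2.16 ± 0.29 and -2.10 ± 0.29. The long noncoding RNA AC005515.1 (chromosome 19, 39685244 to 39694577) was lower, at -6.53 ± 0.61 and -5.94 ± 0.61, and CX3CL1 was at -6.24 ± 0.54 against BI-3812. ADAMTS1, a secreted protease, was higher with FX1 by 3.83 ± 0.38 and 3.17 ± 0.38, the receptor gene IL7R by 3.69 ± 0.51 and 3.03 ± 0.51, CXCL8 by 3.89 ± 0.74 against BI-3812 and SERPINB2 by 3.08 ± 0.72 against BI-3802. BCL6 itself did not differ detectably (-0.05, adjusted p = 0.925, and -0.19, adjusted p = 0.699).

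Of 36 type I interferon genes, 32 were lower with FX1 than with BI-3812 (33 adjusted over the list alone, camera adjusted p = 1.02e-14, adjusted p = 0.05 with an estimated correlation) and 30 than with BI-3802 (33 adjusted over the list alone, camera adjusted p = 2.42e-13, adjusted p = 0.0657 with an estimated correlation). Heat shock genes were higher with FX1, 12 of 16 (13 adjusted over the list alone, camera adjusted p = 1.23e-11, adjusted p = 0.111 with an estimated correlation) and 11 of 16 (14 adjusted over the list alone, camera adjusted p = 1.67e-12, adjusted p = 0.115 with an estimated correlation). Hypoxia genes were higher too, 10 of 18 (11 adjusted over the list alone, camera adjusted p = 1.2e-11, held at 0.00512 with an estimated correlation) and 7 of 18 (8 adjusted over the list alone, camera adjusted p = 4.97e-10, held at 0.00989 with an estimated correlation). Of 22 integrated stress response genes 9 were lower and 1 higher against BI-3812 (10 and 1 adjusted over the list alone, 5 and 4 without preparation 2, camera adjusted p = 0.117) and 10 were lower against BI-3802 (10 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.425 with an estimated correlation). Without the block the numbers against BI-3812 and BI-3802 were 19 and 15 type I interferon, 3 and 0 heat shock, 3 and 2 hypoxia, and 2 and 4 integrated stress response genes. Against BI-3812, 798 genes were higher and 2985 lower (1506 and 1745 under median-of-ratios scaling, all-gene median -0.27, then 0.01), and against BI-3802, 561 and 2835 (1262 and 1378, median -0.30, then 0.02). The first count, 3783, was 935 without the block, 1031 in a fit on only the 2 groups, 1565 and 1029 without preparations 1 and 3, 2294 without the FX1 library of preparation 1 and 2068 without the BI-3812 library of preparation 3. The second, 3396, was 740 without the block, 1174 in a fit on only the 2 groups, 766 and 665 without preparations 1 and 3, 1844 without the FX1 library of preparation 1, and 1916 and 1598 without the BI-3802 libraries of preparations 1 and 3.

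The response to IFNγ left after each compound was measured over the 337 genes that IFNγ raised by at least 1 log2 unit. Of these, ruxolitinib lowered 309 and raised 0 (91.7% lowered), FX1 lowered 264 and raised 4 (78.3%), BI-3812 lowered 28 and raised 15 (8.3%) and BI-3802 lowered 48 and raised 12 (14.2%). The median residual response on the log2 scale is 100% at the level of IFNγ alone. In the fit over all preparations it was 34.8% after ruxolitinib, 28.8% after FX1, 97.7% after BI-3812 and 89.3% after BI-3802. Measured in each preparation, it was 34.5% ± 1.2, 30.3% ± 3.8, 98.5% ± 2.5 and 90.1% ± 12.7 (mean ± SD, n = 3). In the fit over all preparations, the ruxolitinib value turned negative when the fixed IFNγ library fraction was subtracted. That fraction was estimated from genes nearly absent without IFNγ, so a residual near or below 0 follows largely from the construction. The subtraction is thus no test for mixed RNA. If RNA was mixed, the value of 34.8% would not describe inhibited cells, so ruxolitinib and FX1 are not ranked by it. On the linear scale of CPM the median residual was 13.9%, 13.8% and 14.6% in preparations 1, 2 and 3 after ruxolitinib, 11%, 15.6% and 9.9% after FX1, 89.2%, 103.4% and 93.9% after BI-3812, and 50.7%, 92% and 92.9% after BI-3802. The genes were chosen on the shared IFNγ libraries. In 50 simulations of unchanged groups the median residual was 96.5% to 96.7%, below the 97.7% after BI-3812. The block mattered for these percentages, which were 79.3%, 60.3%, 0.6% and 0.6% without it. For BI-3812 the percentage was 3.4%, 4.8% and 1.3% without preparations 1, 2 and 3, 3.3% without the IFNγ library of preparation 1, and 3.3% and 2.4% without the BI-3812 libraries of preparations 2 and 3. For BI-3802 it was 1.3% and 0.9% without preparations 1 and 3, 4.8% without the IFNγ library of preparation 1, and 4.3%, 8.4% and 9.4% without the BI-3802 libraries of preparations 1, 2 and 3.

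**Figure D5:**
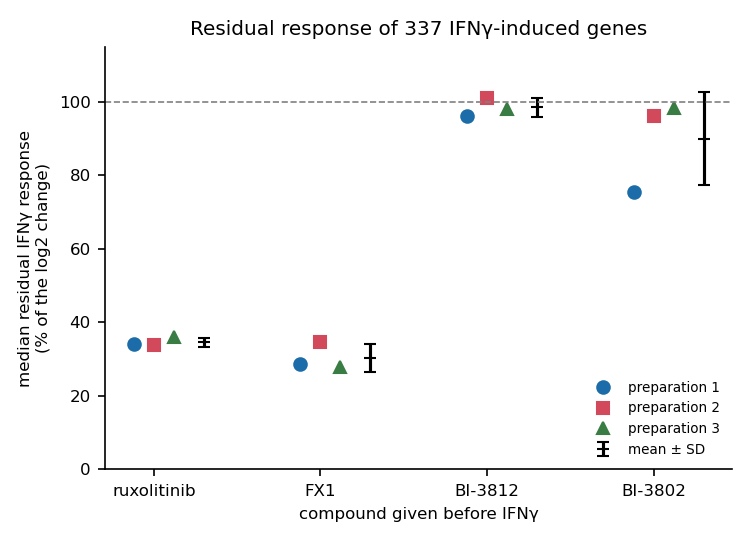
Median residual IFNγ response (percent of the log2 change) over 337 induced genes after each compound, 1 point per preparation with mean ± SD, and a dashed line at 100%. The means are 34.5% after ruxolitinib, 30.3% after FX1, 98.5% after BI-3812 and 90.1% after BI-3802. In the fit over all preparations the ruxolitinib value turned negative when a fixed IFNγ library fraction was subtracted, which follows largely from how the fraction was estimated.

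BCL6 transcript levels were 50.9 ± 14.4 CPM after ruxolitinib, 156 ± 55.9 after FX1, 154 ± 17.9 after BI-3812 and 179 ± 80.1 after BI-3802, against 78.2 ± 9.52 CPM with IFNγ alone. Of the 4 compounds, FX1 (0.92 ± 0.32, adjusted p = 0.0486) and BI-3802 (1.11 ± 0.32, adjusted p = 0.0416, or 0.109 under median-of-ratios scaling) passed, and BI-3812 did not (0.97 ± 0.32, adjusted p = 0.0794). The estimates for FX1, BI-3802 and BI-3812 were close, and BCL6 did not differ detectably between these compounds, so passing does not set BI-3812 apart. Of 15 measured genes known as BCL6 targets in B cells, 3 rose and 6 fell with FX1, 1 rose and 1 fell with BI-3812, and 2 rose and 1 fell with BI-3802 (3 and 6, 3 and 1, and 3 and 1 adjusted over the list alone; 3 and 6, 0 and 0, and 1 and 0 without preparation 2; 1 and 2, 0 and 0, and 0 and 0 without the block; 3 and 5, 0 and 1, and 1 and 1 under median-of-ratios scaling). Their camera adjusted p-values were 0.567, 0.874 and 0.885, and with IFNγ alone 2 rose and 0 fell (4 and 0 adjusted over the list alone), where the median was -0.04 and the mean 0.87 (camera higher, adjusted p = 0.00638, adjusted p = 0.0561 with an estimated correlation; the median was 0.03 under median-of-ratios scaling). BCL6 protein was not measured here.

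The compounds were compared for genes that changed the same way against the shared IFNγ libraries. BI-3812 and BI-3802 shared 469 higher genes (33 for independent lists) and 291 lower genes (11), with 0 in opposite directions. The correlation of their fold changes across genes, which are not independent replicates, was 0.95 (simulated 0.50) and the covariance 0.429. For the other pairs the correlation was near or below the simulated 0.50, at 0.51 for ruxolitinib and FX1, 0.53 and 0.43 for FX1 with BI-3802 and BI-3812, and 0.28 and 0.17 for ruxolitinib with BI-3802 and BI-3812. Ruxolitinib moved 52% and 48.7% of genes in the same direction as BI-3802 and BI-3812, against 66.6% simulated. These percentages depend on scaling and were not computed under median-of-ratios scaling. The all-gene medians were -0.43, 0.16 and 0.15 for ruxolitinib, BI-3802 and BI-3812, and became -0.10, -0.03 and -0.01 under it, while the simulated groups had no such shift. Ruxolitinib and FX1 shared 286 higher genes (112 for independent lists) and 1416 lower genes (649), with 121 in opposite directions and a covariance of 0.399. FX1 shared 252 higher (68) and 243 lower (64) genes with BI-3802 and 140 (43) and 175 (57) with BI-3812, at covariances of 0.322 and 0.251. Ruxolitinib shared 139 higher (86) and 222 lower (126) genes with BI-3802 and 65 (54) and 160 (112) with BI-3812, with 182 and 151 genes in opposite directions and covariances of 0.169 and 0.099. The simulated covariance was 0.07 for each pair, and part of each excess in shared genes may come from the shared IFNγ libraries. The BI-3812 and BI-3802 libraries were also nearly alike in preparations 2 and 3 (SD of the log2 ratio over genes 0.23 and 0.12, against at least 0.416 in the other pairs of 1 preparation outside these compounds), so shared wells or RNA, if present, would also give their overlap and correlation.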

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

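Tests chosen only after the results were seen are limma-voom on the recovered read pairs, the subtraction of a fixed IFNγ library fraction from the ruxolitinib libraries, and the reading of the fit without preparation 2. The planned edgeR and DESeq2 tests of recovered reads were not run, because the values as deposited carry an added 0.0001 and are not themselves multiples of whole reads. limma-voom was run on the read pairs recovered after its removal. Changed-gene counts stayed within 1.5 times of the reported ones under both other pseudocounts, the filter at 5 CPM, median-of-ratios scaling, both other variance priors and limma-voom. Without the block, the counts were 180 for IFNγ against untreated, 2520 for ruxolitinib, 572 for FX1, 19 for BI-3812 and 19 for BI-3802, each against IFNγ, 2501 for ruxolitinib against untreated, and 935 and 740 for FX1 against BI-3812 and BI-3802, and the percentages of induced genes lowered were 79.3%, 60.3%, 0.6% and 0.6%. With only the 2 groups compared, the counts were 1549 for IFNγ, 1122 for FX1, 1540 for BI-3812 and 2444 for BI-3802, and 1031 and 1174 for FX1 against BI-3812 and BI-3802. With no filter, more genes were adjusted for, and the counts were 316 for BI-3812 and 524 for BI-3802 and the percentages lowered 4.6% and 7.8%.

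Leaving out a preparation or a library gave 238 to 331 genes for IFNγ, 2820 to 5403 for ruxolitinib, 341 to 4795 for FX1, 75 to 1042 for BI-3812 and 35 to 564 for BI-3802 against IFNγ, 2631 to 5525 for ruxolitinib against untreated, 1029 to 5032 and 665 to 4722 for FX1 against BI-3812 and BI-3802, and 0 for BI-3802 against BI-3812. The percentages lowered ran from 83.4% to 94.5%, 54.5% to 80.4%, 1.3% to 10.3% and 0.9% to 14.3% for ruxolitinib, FX1, BI-3812 and BI-3802. For ruxolitinib the percentage was 80.4% under median-of-ratios scaling and 94.5% with only the 3 groups needed, and for FX1 84.1% over genes induced by at least 2 log2 units. Apart from the fits without the block, with fewer libraries, with fewer groups or with other genes tested, the cause was not tested.

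Subtracting the fixed IFNγ fraction from the ruxolitinib libraries raised the percentage lowered to 98.2% and turned the median residual response to -12.4%. Against untreated cells it turned the log2 fold changes of IDO1 to -1.18, JAK2 to -2.86, IRF1 to -2.28, SOCS1 to -1.81, CIITA to -0.18, CD74 to -1.05, CXCL10 to -0.10 and CXCL11 to -1.52. The fraction was the median ratio of genes nearly absent without IFNγ, so the subtraction takes such genes to about 0 CPM. It also stops at 0 CPM. Both the changes of sign and the largest negative values therefore follow largely from its construction. No other alternative reversed a residual response or a named gene that passed. Median-of-ratios scaling turned the balance of higher and lower genes, to 2292 and 2103 for ruxolitinib, 282 and 522 for BI-3812 and 427 and 685 for BI-3802 against IFNγ, and 2323 and 1763 for ruxolitinib against untreated. It also turned the sign of some list medians near 0. Leaving out preparation 3 turned the balance too, to 22 and 53 for BI-3812 and 17 and 18 for BI-3802, as did leaving out some single libraries for BI-3812. Depth limits genes below about 0.158 CPM, where 3 read pairs are the floor.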

Other observations

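The tests of the 3 patterns weighed below, on ruxolitinib, preparation 2 and the pair BI-3802 and BI-3812, were chosen only after the results were seen, whereas the splits of the libraries were planned. Some gene groups not described so far also changed. Of 18 endoplasmic reticulum chaperones 7 rose and 0 fell after FX1 (7 adjusted over the list alone, median 0.48, limma camera adjusted p = 6.14e-05, adjusted p = 0.344 with an estimated correlation). After ruxolitinib 3 of them rose (2 adjusted over the list alone, 7 under median-of-ratios scaling, camera adjusted p = 0.00017, adjusted p = 0.383 with an estimated correlation). Of 7 measured aryl hydrocarbon receptor genes 3 rose after FX1 (3 adjusted over the list alone, median 1.32, camera adjusted p = 0.000377, adjusted p = 0.0648 with an estimated correlation). Of 30 proliferation genes 5 fell and 0 rose after FX1 (5 adjusted over the list alone, 2 and 1 without preparation 2, median -0.96, camera adjusted p = 0.0107, adjusted p = 0.697 with an estimated correlation). Of 14 genes downstream of the transcription factors KLF2 and KLF4, 5 fell and 0 rose after ruxolitinib (5 adjusted over the list alone, median -0.39, camera adjusted p = 0.991, with camera pointing higher against the negative median). Under median-of-ratios scaling 2 of these fell and 1 rose, and 1 fell without preparation 2. Of 21 lysosome and autophagy genes 7 rose and 2 fell after ruxolitinib (7 and 2 adjusted over the list alone, 10 and 0 under median-of-ratios scaling, 5 and 1 without preparation 2, camera adjusted p = 0.00138, adjusted p = 0.124 with an estimated correlation). Of 24 measured cholesterol genes 2 rose and 2 fell after ruxolitinib (5 and 0 under median-of-ratios scaling, 0 and 1 without preparation 2, 0 and 0 without the block) and 1 rose after FX1 (2 without preparation 2, 0 without the block), with medians of -0.28 and -0.11 that turned positive under median-of-ratios scaling. Without the block the numbers that rose were 1 and 2 chaperones after FX1 and ruxolitinib, 1 aryl hydrocarbon receptor gene after FX1 and 2 lysosome genes after ruxolitinib, and those that fell were 2 proliferation genes after FX1 and 0 KLF2 and KLF4 genes after ruxolitinib.

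After ruxolitinib, genes nearly absent without IFNγ kept close to a single percentage of the IFNγ library in each preparation, at 16.6%, 16.2% and 18.1%. A residual that differs from gene to gene under JAK inhibition is argued against by the SD of the log2 ratio, at most 0.21 in any preparation, where FX1 gave at least 1.602. A candidate explanation is that RNA of IFNγ-treated cells without the compound made up that percentage of each ruxolitinib library, through mixed wells or mixed RNA; such RNA would keep every other gene above the percentage too, and 2 of 10286 measurements of genes not raised by IFNγ lay below it, against 113 after FX1, 78 after BI-3812 and 57 after BI-3802. In preparations 1, 2 and 3 the numbers were 0, 0 and 2 after ruxolitinib, 99, 4 and 10 after FX1, 25, 39 and 14 after BI-3812 and 27, 14 and 16 after BI-3802, so the contrast with FX1 rests mainly on preparation 1. An equal residual of every induced gene in all cells cannot be told apart from this, since it gives the induced genes 1 ratio as well, and the 2586 measurements of other genes below 50% of the IFNγ level can have a lowest ratio for another reason. Under the mixing explanation the residual response of 34.8% would not describe inhibited cells, and its value after subtraction of the fixed percentage was -12.4%. That percentage was estimated from induced genes, so the negative value is no test of mixing.

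In preparation 2, 13 of 25 endothelial identity genes lay under 5% of the mean of the other preparations in all 6 groups, which argues against endothelial cells like those of preparations 1 and 3 making up at least 5% of it. The other members included 11 that lay over 10% in some group. Cells with a fibroblast profile may have made up preparation 2. Of 9 fibroblast markers, 6 were at least 10 times higher there in all 6 groups, among them DCN at 394 to 1057 CPM. By that rule 0 of 9 smooth muscle markers were, a count that depends on the cutoff. The lowest ratio was 6.82 for NOTCH3 (57 to 728 CPM in preparation 2), 7.29 for ACTG2 (0.5 to 7.69 CPM) and at most 1.67 for the others. Among the fibroblast markers, THY1 passed at 1.13 to 5.46 CPM, and PI16 had a lowest ratio of 0.56. COL1A1 (9844 to 41571 CPM) and COL3A1 (3384 to 22634 CPM) were chosen after their values were seen. They are in the extracellular matrix list and not in the fibroblast list. Endothelial cells that had lost their identity in culture were not tested and stay open. The labels name no sort or gate that would remove other cells. Beyond the endothelial share and the fibroblast profile, no explanation was tested, and no treatment group separates the preparations.

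The BI-3802 and BI-3812 libraries of preparations 2 and 3 were nearly alike, with an SD of the log2 ratio over genes of 0.23 and 0.12, against 0.498 in preparation 1 and at least 0.416 in the other 42 pairs of libraries of 1 preparation. A single library deposited under both names is argued against by the chi-square of read pairs per degree of freedom, 26.68 and 7.3, where sampling alone gives 1. Compounds that act alike in each preparation stay open, since the SD of 0.498 in preparation 1 comes from 1 pair of cultures, and no replicate wells of a treatment give the spread between wells. Wells of preparations 2 and 3 that shared a compound or RNA could give the SD of 0.12 in preparation 3, and cannot be told apart from compounds that act alike, since both give the same values. If wells were shared, the comparison of BI-3802 with BI-3812, which called 0 genes, would rest on preparation 1, and the 469 higher and 291 lower genes that both compounds share would not be independent findings.

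Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In blocked fits on the 6 libraries of each comparison, 1 of the 10 splits, the real one, gave as many genes as observed in 8 comparisons. The real and the highest other counts were 1549 and 0 for IFNγ against untreated, 5416 and 0 for ruxolitinib, 1122 and 0 for FX1, 1540 and 0 for BI-3812 and 2444 and 0 for BI-3802 against IFNγ, 5573 and 3 for ruxolitinib against untreated, and 1031 and 0 and 1174 and 0 for FX1 against BI-3812 and BI-3802. For BI-3802 against BI-3812 the real count was 0, so 10 of 10 splits gave as many. The highest other was 3464, from a split that parted only the pair of preparation 1. With the block, that split measured the difference between the libraries of preparation 1. Its error was the spread within preparations 2 and 3, where the libraries were nearly alike. The 3 other splits that part all 3 pairs gave 0 in that comparison.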
